A study of Mus musculus with 11 samples.

How the data were processed

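RNA of mouse CD8+ T cells was measured on 11 Affymetrix oligonucleotide arrays. Per the labels, the cells came from pmel-1 mice, whose transgenic T cell receptor recognises a peptide of the melanocyte protein gp100. CD8+ cells were enriched as CD44-negative (naive) or CD44-positive (central memory) cells, expanded on antibodies to CD3 and CD28, restimulated once with peptide on allogeneic feeder cells, and cultured for 2 weeks with interleukin 2 (10 cetus units). The resulting effectors then received a final stimulation through CD3 and CD28 for 4 h, or none. There were 3 arrays of memory-derived unstimulated cells, 3 of memory-derived stimulated cells, 2 of naive-derived unstimulated cells and 3 of naive-derived stimulated cells, from 3 independent experiments.

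The deposited values are on a log10 scale, which was inferred here from the values: the sources used here give neither the log base nor the summarization method. The mean deposited value of the hybridization controls was 1.38 for bioB (1.5 pM), 1.87 for bioC (5 pM), 2.58 for bioD (25 pM) and 3.65 for cre (100 pM). The steps were 0.944, 1.02 and 1.77 per unit of log10 concentration, where log2 values would step by 3.32 and natural logarithms by 2.30. The last step exceeds 1, so the base remains an inference, and every fold printed here is on this scale. The submitters' processing notes name Affymetrix Expression Console. The authors had quantile normalized the 11 arrays before deposit: all arrays held the same sorted values, from 0 to 4.56 with a median of 0.554. Array intensity therefore carries no information on depth, values are compressed near 0, detection calls were not used here, and the number of arrays limits the precision.

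Values were multiplied by 3.32, the log2 of 10. After 64 control probe sets were left out, 34945 probe sets had 1 gene symbol, 932 had several and 9211 were not listed in the annotation used here. Only those with 1 symbol were named. Of these, 34754 had a gene identifier that matched the gene table, and 0 symbols changed. The 18193 genes were each represented by the probe set with the highest mean, and 14795 genes whose probe set lay above the array's 40th percentile on at least 2 arrays were tested. That level is 1.54 on the log2 scale, and where all arrays of a group lay below it a change is given as a bound counted from it. Of the genes named in each comparison whatever their result, 11 had such a probe set, and 2 were not analysed here.

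A linear model over the 4 groups was fitted to all 11 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes; 7 residual and 3.86 prior degrees of freedom). The comparisons were stimulation within each origin, origin (naive-derived minus memory-derived) within each stimulation state, and the interaction, which tests whether the response to stimulation differed between origins. P values are from limma, two-sided and adjusted by Benjamini and Hochberg within a comparison, and a gene passed at an adjusted p below 0.05. Among 14795 genes, chance alone gives 740 at an unadjusted p below 0.05. Errors are standard errors (SE) of the fitted log2 difference or standard deviations (SD) between arrays. Figures were drawn with matplotlib 3.10.9 (numpy 2.4.6) in Python 3.11.15.

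The replicate number is the number of the experiment, so it pairs arrays across groups. Deviations from the group mean correlated at -0.0717 to 0.112 between arrays of the same experiment (median 0.0341, 15 pairs) and at -0.131 to 0.112 between arrays of different experiments (median -0.00361, 30 pairs). Deviations within a group sum to 0, so these pairs are tied and are not separate observations. For example, naive-derived stimulated array 1 correlated at 0.112 with naive-derived unstimulated array 1 and at -0.112 with array 2 of that group. The consensus correlation within an experiment, over all groups, was -0.00597, and the model holds no replicate block. Stimulated and unstimulated arrays of the same origin and experiment correlated at 0.047 to 0.112, above 0 in every such pair. A block by origin and experiment was not fitted, so this pairing is not taken into account. A model with the replicate block was fitted as an alternative, and its value stands beside a result where it ends a call or moves a count by more than 1.5 times.

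Tests on 29 fixed gene lists used camera from limma with a preset correlation of 0.01, two-sided and adjusted over the 29 lists within a comparison. The lists cover T cell activation, effector function, signalling, migration, metabolism, growth and division, and markers of other cell types. The adjusted p with a correlation estimated from the data stands beside each call, as does the count of members when p values were adjusted over the list alone. With the estimated correlation, 0 lists passed in any comparison.

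The comparisons, the gene lists and the rule for naming genes were chosen before the data were examined. The rule takes, per comparison, the 6 largest increases and the 6 largest decreases among genes that passed and whose values did not overlap between the groups (this condition was not used for the interaction), up to 3 members of each list that passed with the smallest p, and 13 genes whatever their result. Some of these genes are left out of the text. Probe sets of near-identical gene families are named as such, since they may hybridize to related transcripts.

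The model was tested on simulated data in which 67, 67 and 66 of 14795 genes were given log2 changes of 0.5, 1 and 2. It recovered 16.4%, 67.2% and 97% of them in the design of the stimulation in memory-derived effectors, and 7.46%, 50.8% and 87.9% in that of the stimulation in naive-derived effectors. For the interaction the shares were 0%, 29.9% and 77.3%. The alternatives tried were another normalization, other filters and choices of probe set, a trended and robust or array-weighted fit, the replicate block as a fixed or random term, a fit to the compared groups alone, a minimum log2 change of 1 among the genes that passed, experiments 1 and 2 only, and leaving out each array in turn. A scaling of each array to its hybridization controls was added after seeing the data.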

Results

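Gene expression was compared between CD8+ effector T cells grown from naive or from central memory cells of pmel-1 mice, with or without a final 4 h stimulation through CD3 and CD28. On the 11 arrays, 14795 genes were tested. Memory-derived cells had 3 unstimulated and 3 stimulated arrays, and naive-derived cells had 2 unstimulated and 3 stimulated arrays. The first principal component of the tested genes held 56.5% of the variance. On it the 3 memory-derived unstimulated arrays lay at 50.4, 40.3 and 77.4, and the arrays of the other 3 groups lay between -37.45 and -11.6. The 2 naive-derived unstimulated arrays, at -16.2 and -16.7, were thus on the side of the stimulated arrays. A sign of RNA quality, the 3' minus 5' difference of actin (log10), did not overlap between the groups of any of the 4 comparisons below of stimulation or origin: it was 0.263 to 0.351 on memory-derived unstimulated, 0.431 to 0.520 on memory-derived stimulated, 0.462 to 0.478 on naive-derived unstimulated and 0.581 to 0.782 on naive-derived stimulated arrays. Its effect on the counts was not tested.

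**Figure D1:**
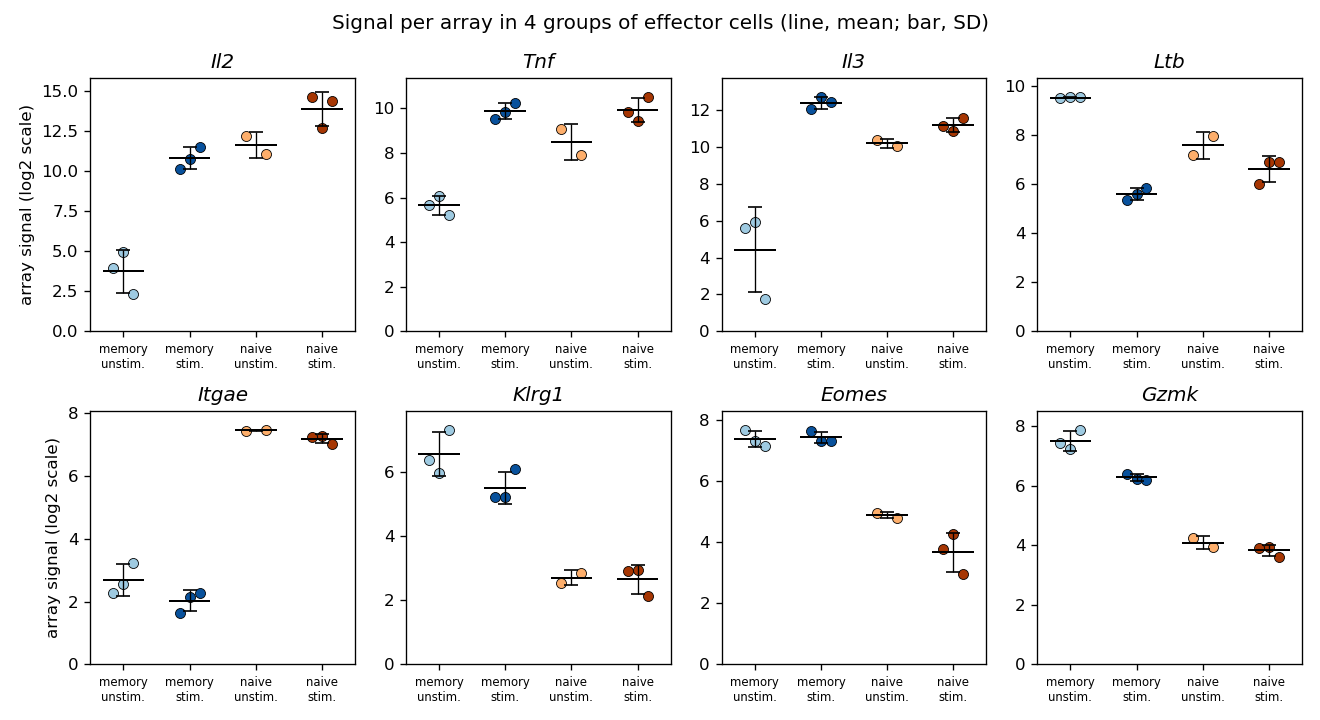
Log2 values of single genes on each array, by group (points are arrays, lines are group means, bars are SDs). Itgae stood at 7.19 ± 0.139 (SD) in naive-derived and 2.03 ± 0.339 in memory-derived stimulated cells, while Il2 was low in the memory-derived unstimulated group (3.74 ± 1.33).

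The first comparison asked what the final stimulation changed in memory-derived effectors. Cytokine genes rose most: Il2, the T cell growth factor, rose by 7.05 on the log2 scale (SE 0.68, n = 3 and 3), from 3.74 ± 1.33 to 10.79 ± 0.694 (SD). Il3, a growth factor of blood progenitors, rose by 7.94 (SE 0.835), and Tnf, an inflammatory cytokine, by 4.20 (SE 0.348). Il1a, another, lay below the filter level (1.54) on all 3 unstimulated arrays and rose by at least 4.84, counted from that level. Ltb, which encodes lymphotoxin beta, fell by 3.93 on the log2 scale (SE 0.268), and Fgl2, an inhibitory fibrinogen-like protein of T cells, fell by 3.32. Of 23 secreted cytokines and chemokines tested, 11 rose and 2 fell (13 and 2 adjusted over the list alone; camera adjusted p = 8.87e-05, and adjusted p = 0.408 with an estimated correlation). Memory-derived unstimulated array 3 stood apart from its group, with this list at -1.09 relative to the group mean against 0.436 and 0.655 on the other arrays, and without it Il3 rose by 6.61. It was also apart for other lists: without it the mean change went from 1.89 to 1.34 for cytokines, from 1.31 to 1.04 for activation markers, from 1.21 to 0.87 for ribosome biogenesis, from -1.14 to -0.90 for mitosis and from -0.70 to -0.50 for DNA replication, and 25 ribosome biogenesis genes rose and 21 mitosis genes fell.

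Genes of T cell activation rose together. Of 22 activation markers and costimulatory TNF family members, 13 rose and 1 fell (14 and 1 adjusted over the list alone; adjusted p = 6.77e-07, and adjusted p = 0.348 with an estimated correlation). Among them were Tnfrsf4, the receptor OX40, at 2.47 (SE 0.258), Tnfsf14, the ligand LIGHT, at 2.50 (SE 0.317), and Cd70, the ligand of CD27, at 3.65 (SE 0.411). Of 36 immediate early transcription factors and phosphatases, 18 rose and 2 fell (19 and 3 adjusted over the list alone; adjusted p = 4.11e-05, and adjusted p = 0.516 with an estimated correlation), with Fosl1 at 2.73, Ier3 at 2.68 and Irf4, which drives effector differentiation, at 2.12. NF-kappaB pathway genes did not pass as a list (8 of 18 higher and 4 lower, 10 and 5 adjusted over the list alone; adjusted p = 0.0805). Single members rose, such as Nfkbid at 3.77, Rel, a subunit of the factor, at 2.40 and Cflar, an inhibitor of caspase 8, at 2.43. Stat5a, which transmits interleukin 2 signals, rose by 2.88.

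Genes of growth and biosynthesis rose as well. All 26 ribosome biogenesis genes tested rose, the same count adjusted over the list alone (adjusted p = 9.98e-12, and adjusted p = 0.408 with an estimated correlation), among them Ncl, a nucleolar protein, at 1.30 (SE 0.192) and Polr1a, the largest subunit of RNA polymerase I, at 1.27 (SE 0.175). Of 20 genes of the amino acid response and serine synthesis, 17 rose and 1 fell (17 and 2 adjusted over the list alone; adjusted p = 9.98e-12, and adjusted p = 0.261 with an estimated correlation), including Asns, asparagine synthetase, at 2.11 and Mthfd2, a mitochondrial folate enzyme, at 1.90. Of 20 genes of the unfolded protein and heat shock response, 11 rose and 1 fell (11 and 2 adjusted over the list alone; adjusted p = 0.000344, and adjusted p = 0.348 with an estimated correlation), such as Hspa5, the endoplasmic reticulum chaperone BiP, at 1.52.

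Genes of cell division, of the interferon response and of adhesion fell. Of 26 mitosis genes, 24 fell and 0 rose (25 and 0 adjusted over the list alone; adjusted p = 1.08e-10, and adjusted p = 0.408 with an estimated correlation). The spindle protein gene Nusap1 fell by 2.05 on the log2 scale, and the change was -1.77 for Birc5, which encodes survivin. Of 25 DNA replication genes, 15 fell and 0 rose (18 and 0 adjusted over the list alone; adjusted p = 5.22e-06, and adjusted p = 0.516 with an estimated correlation), with Tk1, thymidine kinase, at -1.88 and Mcm7, a subunit of the replicative helicase, at -1.58. Of 26 type I interferon response genes, 16 fell and 0 rose (17 and 0 adjusted over the list alone; adjusted p = 1.46e-06, and adjusted p = 0.225 with an estimated correlation), such as Rtp4 at -2.17 and Isg20, an antiviral exonuclease, at -1.40. Of 22 genes of integrins, selectin ligand enzymes and adhesion, 11 fell and 2 rose (13 and 2 adjusted over the list alone; adjusted p = 0.00106, and adjusted p = 0.225 with an estimated correlation), with Selplg, the P-selectin ligand, at -1.76. Single receptors also fell, among them Ccr2, a chemokine receptor of effector cells, at -3.03, Ifngr1, an interferon gamma receptor chain, at -2.49, and Tgfbr2, a TGF-beta receptor chain, at -2.26.

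In all, 4675 genes passed in this comparison, 2119 higher and 2556 lower after stimulation, and 1330 of them changed at least 2-fold. Scaling to the hybridization controls moved the share of higher genes from 45.3% to 41.2%. Among genes chosen in advance as effector and memory genes, Ifng (1.49, SE 0.849, adjusted p = 0.218, and 0.12 without memory-derived unstimulated array 3), Gzmb (-0.24, adjusted p = 0.214), Cd27 (-0.02, adjusted p = 0.949) and Eomes (0.06, adjusted p = 0.903) did not pass. Several others passed only narrowly. Cd44, the adhesion receptor used for the enrichment, rose by 0.86 (adjusted p = 0.0147, and 0.0514 without memory-derived stimulated array 2). Prf1, perforin, rose by 1.12 (adjusted p = 0.0378) and by 0.73 without memory-derived unstimulated array 3 (adjusted p = 0.148). Klrg1, a receptor of terminal effectors, had a change of -1.05 (adjusted p = 0.0454, and 0.0583 with the replicate block), and of -0.67 without that array (adjusted p = 0.176). Il7r, the interleukin 7 receptor, had a change of -0.82 (adjusted p = 0.0417, and 0.149 without memory-derived unstimulated array 1). Tbx21, which encodes T-bet, had a change of 0.47 (adjusted p = 0.0227, 0.071 without memory-derived stimulated array 1, and 0.0769 with control scaling). Over all alternatives the adjusted p ranged from 0.00508 to 0.0705 for Cd44, 0.00707 to 0.148 for Prf1, 0.0136 to 0.176 for Klrg1, 0.00551 to 0.266 for Il7r and 0.00459 to 0.0769 for Tbx21, and leaving out 1 array ended the call in 1, 5, 8, 7 and 5 of 11 cases.

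The second comparison asked the same of naive-derived effectors, with 3 stimulated and 2 unstimulated arrays. Il2 stood at 11.61 ± 0.805 (SD, n = 2) without the final stimulation and 13.86 ± 1.06 (n = 3) with it, a log2 difference of 2.25 (SE 0.761) that did not pass (adjusted p = 0.477). Of the 2 genes that passed, Fgl2 fell by 2.41 on the log2 scale (SE 0.294, adjusted p = 0.0417). The other, H2-Q2, a class I histocompatibility gene of a near-identical family (adjusted p = 0.0325), lay below the filter level of 1.54 on all 5 naive-derived arrays and had been tested only because of memory-derived arrays, so its change is not taken as a result. Neither passed with the replicate block (adjusted p = 0.0814 and 0.142; 0 genes in limma, 1354 at an unadjusted p below 0.05), and neither passed without naive-derived unstimulated array 2 (adjusted p = 0.283 and 0.251). Each call was lost in 9 of the 11 cases that left out 1 array, and over all alternatives the adjusted p of either ranged from 0.0086 to 0.477. With all arrays, 1252 genes had an unadjusted p below 0.05.

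Whole lists nevertheless differed in the naive-derived arrays. The list of 20 genes of the amino acid response and serine synthesis shifted up after stimulation, with a median of 0.55. Of its genes, 0 passed over all genes and 12 rose adjusted over the list alone (camera adjusted p = 2.45e-15, and adjusted p = 0.407 with an estimated correlation). No member passed over all genes in the other lists called. The 18 NF-kappaB genes (2 higher adjusted over the list alone; adjusted p = 0.00776) and the 22 activation markers (0 adjusted over the list alone; adjusted p = 0.0345) shifted up, and each had an adjusted p = 0.906 with an estimated correlation. The 26 mitosis genes (0 adjusted over the list alone; adjusted p = 0.00142) and the 25 DNA replication genes (0 adjusted over the list alone; adjusted p = 0.0345) shifted down, each with an adjusted p = 0.906 with an estimated correlation. The 26 type I interferon response genes shifted down (2 lower adjusted over the list alone; adjusted p = 0.00169, and adjusted p = 0.522 with an estimated correlation). So did the 8 markers of CD4, regulatory, gamma-delta T and NK cells (1 lower adjusted over the list alone; adjusted p = 0.0345, and adjusted p = 0.407 with an estimated correlation). With experiments 1 and 2 only, 4 of these 7 calls were lost: mitosis (adjusted p = 0.0608), DNA replication (0.0891), activation markers (0.0891) and the markers of CD4, regulatory, gamma-delta T and NK cells (0.062).

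Of the other genes named in advance, none passed in naive-derived cells: the log2 differences were 1.44 for Tnf (adjusted p = 0.328), -1.22 for Eomes (0.295), 0.62 for Gzmb (0.268), -0.60 for Prf1 (0.751), 0.35 for Ifng (0.959), -0.32 for Cd27 (0.739), -0.18 for Il7r (0.928), 0.09 for Tbx21 (0.922), 0.04 for Cd44 (0.988) and -0.04 for Klrg1 (0.993). The test for Ifng used a spread shared over groups, which memory-derived unstimulated cells raised (SD 2.39). In the naive-derived groups the SD was 0.073 and 0.12, so this result does not show that Ifng was unchanged. Tnf stood at 9.06 and 7.93 on the unstimulated arrays, and Prf1 at 8.25, 8.11 and 7.27 on the stimulated ones. These differences thus leaned on single arrays. The memory-derived and naive-derived responses, computed on separate arrays, correlated at r = 0.414 across all genes tested, which are not independent replicates. Of the 4675 genes that passed in memory-derived cells, 79.4% had the same sign in naive-derived cells, and the slope of the naive-derived on the memory-derived changes was 0.197. Relative to the memory-derived unstimulated mean, the activation marker list stood at 1.39 in naive-derived unstimulated, 1.31 in memory-derived stimulated and 1.64 in naive-derived stimulated arrays. The ribosome biogenesis list stood at 1.21, 1.21 and 1.32 in the same groups.

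**Figure D2:**
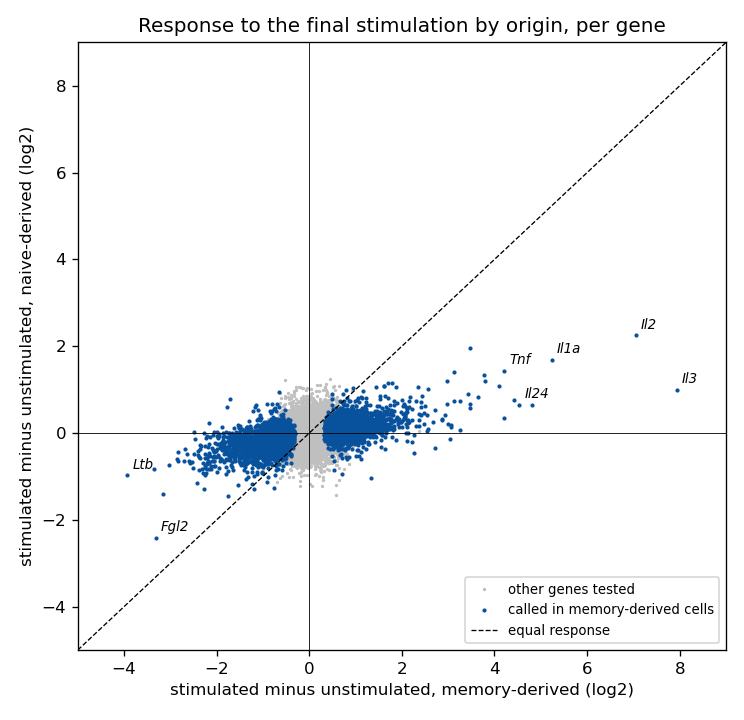
Log2 change after stimulation in naive-derived against memory-derived effectors, 1 point per gene. Over the 4675 genes that passed in memory-derived effectors the slope was 0.197.

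The interaction tested whether the response to stimulation differed by origin. The named differences below 0 were largest for the cytokine genes Il3, Il2, Il24, Il10, Il1a and Il23a: the interaction (naive-derived minus memory-derived response, log2) was -6.95 for Il3 (SE 1.25, adjusted p = 0.0268) and -4.80 for Il2 (SE 1.02, adjusted p = 0.0411). For Tnf it was -2.77 (SE 0.522, adjusted p = 0.0301). It was 2.95 for Ltb (SE 0.402, adjusted p = 0.0166), which fell less. In total 401 genes passed, 239 with a positive and 162 with a negative difference. The share that was positive was 59.6%, and 49% with control scaling. With the replicate block 26 genes passed, all of them among the 401; Ltb (adjusted p = 0.0267) was one, and Il3 (0.064), Il2 (0.0904) and Tnf (0.0658) were not. Over all alternatives the adjusted p ranged from 0.00223 to 0.0827 for Ltb, 0.000733 to 0.122 for Il3, 0.0129 to 0.154 for Il2 and 0.0113 to 0.131 for Tnf.

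The interaction was negative for lists that rose in memory-derived cells. It subtracts the memory-derived response, taken from the same arrays, and the naive-derived response was smaller. The signs of these lists therefore largely repeat the memory-derived comparison, including the deviation of memory-derived unstimulated array 3. They are not separate support for it. Of 26 ribosome biogenesis genes, 3 were lower and 0 higher (19 and 0 adjusted over the list alone; adjusted p = 9.27e-12, and adjusted p = 0.482 with an estimated correlation). Of 20 genes of the amino acid response, 6 were lower and 1 higher (14 and 2 adjusted over the list alone; adjusted p = 6.25e-08, and adjusted p = 0.427 with an estimated correlation). The counts were 6 and 0 of 36 immediate early genes (11 and 0 adjusted over the list alone; adjusted p = 2.18e-06, and adjusted p = 0.482 with an estimated correlation), 2 and 0 of 22 activation markers (12 and 0 adjusted over the list alone; adjusted p = 6.02e-06, and adjusted p = 0.482 with an estimated correlation), and 4 and 1 of 23 cytokines (8 and 1 adjusted over the list alone; adjusted p = 0.000205, and adjusted p = 0.482 with an estimated correlation). Of 20 genes of the unfolded protein response, 1 was lower and 0 higher (8 and 0 adjusted over the list alone; adjusted p = 9.28e-05, and adjusted p = 0.427 with an estimated correlation). With the replicate block these 6 lists still passed (adjusted p from 7.98e-11 to 0.000397), but 0 of their members were lower over all genes (limma; 3080 of all genes tested at an unadjusted p below 0.05) and 1, a cytokine, was higher. With control scaling 0 ribosome biogenesis genes, 7 amino acid response genes and 4 activation markers were lower, and 0 amino acid response genes were higher.

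The interaction was positive for lists in which more members fell than rose in memory-derived cells, which for the same reason is not separate support. No mitosis gene passed over all genes (13 higher adjusted over the list alone; adjusted p = 6.25e-08, and adjusted p = 0.482 with an estimated correlation). Of 26 type I interferon genes 6 were higher (7 adjusted over the list alone; adjusted p = 0.000177, and adjusted p = 0.427 with an estimated correlation). DNA replication genes (0 over all genes, 5 adjusted over the list alone; adjusted p = 0.000211), integrins and adhesion genes (0, and 3 adjusted over the list alone; adjusted p = 0.0141) and chemokine receptors (1, and 5 adjusted over the list alone; adjusted p = 0.0259) also passed as lists. Their values were adjusted p = 0.555, adjusted p = 0.427 and adjusted p = 0.482 with an estimated correlation. Under the replicate block 1 interferon gene and 0 chemokine receptors were higher, and under control scaling 2 of each. Of the genes named in advance, Gzmb passed narrowly (0.86, SE 0.2, adjusted p = 0.0497, 0.0975 with the replicate block, and 0.0151 to 0.159 over all alternatives). Not passing were Prf1 (-1.72, adjusted p = 0.102, 0.0263 without memory-derived unstimulated array 2, and up to 0.291 in other alternatives), Eomes (-1.28, 0.105), Cd44 (-0.83, 0.179), Klrg1 (1.01, 0.284), Tbx21 (-0.38, 0.293), Il7r (0.65, 0.373), Cd27 (-0.30, 0.562) and Ifng (-1.14, 0.637). The sign for Ifng rested on memory-derived unstimulated array 3, without which the interaction was 0.23. Klrg1 stood at 7.31 on that array against 6.38 and 5.97 on arrays 1 and 2, so the size of its difference also leaned on it.

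The interaction count moved widely when 1 array was left out, which also lowers the precision. It was 0 without naive-derived unstimulated array 1 (limma; 2600 at an unadjusted p below 0.05) and 15 without array 2 of that group. It was 75, 19 and 35 without memory-derived stimulated arrays 1, 2 and 3, and 53, 36 and 210 without naive-derived stimulated arrays 1, 2 and 3. It was 187 without memory-derived unstimulated array 1, 1505 without array 2 and 482 without array 3 of that group. Leaving out a naive-derived unstimulated array left 1 in that group, so the low counts there need not reflect the array left out.

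The next comparison asked how effectors of different origin differed without a final stimulation, with 2 naive-derived and 3 memory-derived arrays. It subtracts the same memory-derived unstimulated arrays as the first comparison did. Lists that moved the same way in both are therefore not separate support, and origin cannot be told apart there from the state of activation. Cytokine genes were higher in naive-derived cells: Il2 by 7.87 on the log2 scale (SE 0.761, n = 2 and 3), Il10, an immunoregulatory cytokine, by 6.94 (SE 0.632) and Tnf by 2.84 (SE 0.389). Itgae, the integrin CD103 that binds E-cadherin on epithelium, was higher by 4.77 (SE 0.267), and Tnfrsf4 by 4.67 (SE 0.289). Klrg1 was lower by 3.85 (SE 0.399), and Gzmk, granzyme K, was lower by 3.41 (SE 0.199). Eomes, a transcription factor of memory and cytotoxic cells, was lower by 2.50 (SE 0.307).

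Inhibitory receptors were among the genes higher in naive-derived unstimulated cells. Of 12 tested, 6 were higher and 2 lower (7 and 2 adjusted over the list alone; adjusted p = 0.00758, and adjusted p = 0.296 with an estimated correlation), with Pdcd1, the receptor PD-1, at 2.66 (SE 0.206), Lag3 at 2.12 (SE 0.16) and Cd160 at 1.55 (SE 0.178). Of 23 cytokines and chemokines, 12 were higher and 1 lower (15 and 1 adjusted over the list alone; adjusted p = 5.73e-07, and adjusted p = 0.296 with an estimated correlation). Of 22 activation markers, 14 were higher and 0 lower (16 and 1 adjusted over the list alone; adjusted p = 1.55e-07, and adjusted p = 0.296 with an estimated correlation), such as Cd200, an immunoregulatory ligand, at 2.65. Of 36 immediate early genes, 18 were higher and 2 lower, the same adjusted over the list alone (adjusted p = 4.04e-05, and adjusted p = 0.559 with an estimated correlation), including Irf4 at 2.18 and Batf, its partner, at 1.27. The counts were 11 and 3 with the replicate block, and 14 and 5 without memory-derived unstimulated array 3. Of 18 NF-kappaB genes, 7 were higher and 2 lower (8 and 3 adjusted over the list alone; adjusted p = 0.0229, and adjusted p = 0.571 with an estimated correlation), a call lost with experiments 1 and 2 only (adjusted p = 0.0717).

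Biosynthesis genes were higher in naive-derived unstimulated cells too. Of 26 ribosome biogenesis genes, 23 were higher and 0 lower (26 and 0 adjusted over the list alone; adjusted p = 5.55e-12, and adjusted p = 0.381 with an estimated correlation), with Ncl at 1.46. Of 20 genes of the amino acid response, 15 were higher and 1 lower (16 and 1 adjusted over the list alone; adjusted p = 2.28e-08, and adjusted p = 0.296 with an estimated correlation), with Shmt2, a mitochondrial serine enzyme, at 1.24. Of 20 genes of the unfolded protein response, 11 were higher and 0 lower (12 and 0 adjusted over the list alone; adjusted p = 9.62e-06, and adjusted p = 0.296 with an estimated correlation), with Hspa5 at 1.68, and 7 were higher with control scaling.

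Lower in naive-derived unstimulated cells were 10 of 26 mitosis genes, with 0 higher (15 and 0 adjusted over the list alone; adjusted p = 3.5e-05, and adjusted p = 0.571 with an estimated correlation), such as Nusap1 at -1.90. In the fit with the replicate block 4 mitosis genes were lower. Without memory-derived unstimulated array 3, 5 were lower and the mean difference of the list went from -0.72 to -0.48. Of 23 terminal effector genes, 10 were lower and 3 higher (11 and 4 adjusted over the list alone; adjusted p = 0.00517, and adjusted p = 0.381 with an estimated correlation), with Ccr2 at -3.56 and S100a4, a calcium-binding protein, at -1.34, and without that array 9 were lower and 1 higher. Of 22 integrin and adhesion genes, 9 were lower and 1, Itgae, was higher (11 and 1 adjusted over the list alone, and 9 and 2 without that array; adjusted p = 0.0288, and adjusted p = 0.296 with an estimated correlation), with Itgb1, the beta 1 integrin chain, at -1.86. Chemokine receptors did not pass as a list (7 of 19 lower and 1 higher, 8 and 1 adjusted over the list alone, with camera adjusted p = 0.0564). They passed, lower in naive-derived cells, with the replicate block (adjusted p = 0.0282) and with experiments 1 and 2 only (0.0454). NK cell receptors did not pass as a list either (5 of 17 lower and 1 higher, 6 and 1 adjusted over the list alone, with adjusted p = 0.0564). The list passed, lower in naive-derived cells, with the replicate block (adjusted p = 0.0051) and with experiments 1 and 2 only (0.00434). Klre1 was lower by 2.23 and Klra7, of a near-identical family, was lower by 3.89. Granzyme genes of a near-identical family were also lower, at -4.14 for Gzmd (adjusted p = 0.0126, 0.141 without naive-derived unstimulated array 2, and 0.00277 to 0.141 over all alternatives) and -3.90 for Gzme (adjusted p = 0.00312).

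In total 3819 genes passed, 1611 higher and 2208 lower in naive-derived unstimulated cells, and 1293 differed at least 2-fold. Control scaling moved the share of higher genes from 42.2% to 32.5%. Without naive-derived unstimulated array 1 or 2 the count was 1946 or 1843. Of the other genes named in advance, Il7r was lower by 1.40 (adjusted p = 0.00763, 0.06 without naive-derived unstimulated array 1, and 0.00168 to 0.06 over all alternatives) and Tbx21 was higher by 0.92 (adjusted p = 0.00193). Not passing were Ifng (2.26, SE 0.95, adjusted p = 0.107; 3.08 and 0.0344 without memory-derived unstimulated array 1, 0.89 and 0.022 without array 3, and an adjusted p up to 0.284 in other alternatives), Cd27 (0.56, adjusted p = 0.0688; 0.0317 without memory-derived unstimulated array 1, and up to 0.312 in other alternatives), Gzmb (-0.10, 0.677), Prf1 (-0.18, 0.8) and Cd44 (0.04, 0.936).

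The last comparison asked how effectors of different origin differed after the final stimulation, with 3 arrays each. Itgae was higher in naive-derived cells by 5.17 on the log2 scale (SE 0.239, adjusted p = 2.07e-06), at 7.19 ± 0.139 (SD, n = 3) against 2.03 ± 0.339 (n = 3). Eomes was lower by 3.77 (SE 0.275), Klrg1 was lower by 2.84 (SE 0.357) and Gzmk was lower by 2.45 (SE 0.178). Il10 was higher by 3.09 (SE 0.565, adjusted p = 0.012, 0.0503 without memory-derived stimulated array 3, and 0.00295 to 0.0503 over all alternatives). Il2 was higher by 3.07 (SE 0.68, adjusted p = 0.0314), a call lost with the replicate block (adjusted p = 0.0647) and without memory-derived stimulated array 1 (0.121), with a range of 0.00585 to 0.121 over all alternatives.

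Inhibitory receptors were again among the higher genes. Of 12 tested, 5 were higher and 1 lower (6 and 1 adjusted over the list alone; adjusted p = 6.46e-05, and adjusted p = 0.0547 with an estimated correlation), with Ctla4, a competitor of CD28, at 2.67 (SE 0.387), Pdcd1 at 2.01 (SE 0.184) and Lag3 at 1.97 (SE 0.143). Of 26 type I interferon response genes, 9 were higher and 0 lower (10 and 0 adjusted over the list alone; adjusted p = 3.24e-07, and adjusted p = 0.125 with an estimated correlation), among them Ifi27l2a at 2.67, Zbp1, a nucleic acid sensor, at 1.41 and Isg20 at 1.40. Of 21 genes of the T cell receptor complex and proximal signalling, 3 were higher and 1 lower, the same adjusted over the list alone (adjusted p = 0.0165, and adjusted p = 0.125 with an estimated correlation), with Cd8a, a coreceptor chain, at 1.23. Fitted with the replicate block, 3 of these were higher and 0 lower, and with experiments 1 and 2 only the list did not pass (adjusted p = 0.0602). Of 23 cytokines, 4 were higher and 0 lower (5 and 0 adjusted over the list alone; adjusted p = 0.00265, and adjusted p = 0.531 with an estimated correlation), including Il21 at 1.40. Of 22 activation markers, 2 were higher, Tnfrsf4 at 2.66 and Cd200 at 3.02, and 0 lower, the same count adjusted over the list alone (adjusted p = 0.0313, and adjusted p = 0.624 with an estimated correlation). Markers of MHC class II presentation were higher in 3 of 8 genes, the same adjusted over the list alone (adjusted p = 0.00134, and adjusted p = 0.125 with an estimated correlation), with H2-DMa at 1.14. Of 25 DNA replication genes, 0 passed over all genes or adjusted over the list alone, and the list shifted up (adjusted p = 0.0102, and adjusted p = 0.655 with an estimated correlation). Its median was 0.20, and 0.091 with control scaling. The NF-kappaB list also shifted up with 0 of 18 genes passing over all genes and 1 adjusted over the list alone (adjusted p = 0.0272, and adjusted p = 0.633 with an estimated correlation).

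Effector genes were among the lower ones. Of 23 terminal effector genes, 6 were lower and 0 higher (11 and 3 adjusted over the list alone; adjusted p = 0.00383, and adjusted p = 0.397 with an estimated correlation), with Ccr2 at -1.28 and Anxa2, a membrane-binding annexin, at -1.09. Of 23 cytotoxic granule and death ligand genes, 7 were lower and 2 higher (10 and 4 adjusted over the list alone; adjusted p = 0.0374, and adjusted p = 0.624 with an estimated correlation). With control scaling 9 were lower and 0 higher, and with experiments 1 and 2 only the list did not pass (adjusted p = 0.0878). The lower ones included near-identical granzymes, such as Gzmd at -5.06 (SE 0.905, adjusted p = 0.011), and Prf1 at -1.90 (adjusted p = 0.0161, 0.0642 without naive-derived stimulated array 3, and 0.00354 to 0.0683 over all alternatives). Gzmd varied widely between naive-derived cultures. It stood at 9.56, 6.60 and 5.64 on stimulated arrays 1, 2 and 3 and at 9.61 and 6.86 on unstimulated arrays 1 and 2. Memory-derived stimulated arrays stood at 11.85, 12.15 and 12.98. Relative to the memory-derived unstimulated mean, the whole list stood at -0.396, -0.973 and -1.29 on the naive-derived stimulated arrays. Gzmb, granzyme B, was higher by 0.76 (adjusted p = 0.0106, 0.0516 without memory-derived stimulated array 2, 0.0829 with control scaling, and 0.00299 to 0.0829 over all alternatives). NK cell receptors did not pass as a list (3 of 17 lower and 1 higher, 4 and 2 adjusted over the list alone; adjusted p = 0.0803), but passed with the replicate block (adjusted p = 0.0288, 4 lower), and had an adjusted p of 0.304 with experiments 1 and 2 only. Klre1 was lower by 2.44 and Tyrobp, an adaptor of activating receptors, was lower by 1.68.

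In total 548 genes passed, 250 higher and 298 lower in naive-derived stimulated cells, and 238 differed at least 2-fold. Control scaling moved the median of all genes from -0.01 to -0.12 and the share of higher genes from 45.6% to 31.1%, so the directions above are relative to the typical gene. With that scaling 5 interferon response genes, 1 T cell receptor complex gene and 1 MHC class II gene were higher. Without memory-derived stimulated arrays 1 and 3 the count was 287 and 298, without array 2 of that group 322, and without naive-derived stimulated array 3 it was 306. The 3' minus 5' difference of GAPDH was -0.548 to -0.444 (log10) on naive-derived and -0.431 to -0.417 on memory-derived stimulated arrays, the opposite direction to that of actin. Of the other genes named in advance, Tnf (0.07, adjusted p = 0.947), Il7r (-0.75, 0.194), Cd27 (0.27, 0.532), Cd44 (-0.79, 0.0936), Ifng (1.12, 0.574) and Tbx21 (0.54, 0.0564) did not pass. Without memory-derived unstimulated array 3, which enters through the shared spread, Cd44 (0.0302), Ifng (0.00953) and Tbx21 (0.0427) passed; over all alternatives their adjusted p reached 0.252, 0.731 and 0.251.

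Many genes that passed for origin did so in both stimulation states, which use separate arrays of the same experiments. Of the 548 genes that passed after stimulation, 375 also passed without it: 159 were higher in both, where 27.2 would be for independent lists, 207 were lower in both, where 44.5 would be, and 9 had opposite signs. Of the 548, 90.1% had the same sign in unstimulated cells, and across all genes tested the differences correlated at r = 0.466. Genes are not independent replicates, and both tests share each gene's estimate of spread. Stimulated and unstimulated arrays of the same origin and experiment are paired, and their deviations correlated at 0.047 to 0.112 in all 5 pairs, which the numbers for independent lists leave out. Itgae, Pdcd1, Lag3, Tnfrsf4 and Cd200 were higher and Klrg1, Eomes, Gzmk, Klre1 and Ccr2 were lower in naive-derived cells in both states.

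**Figure D3:**
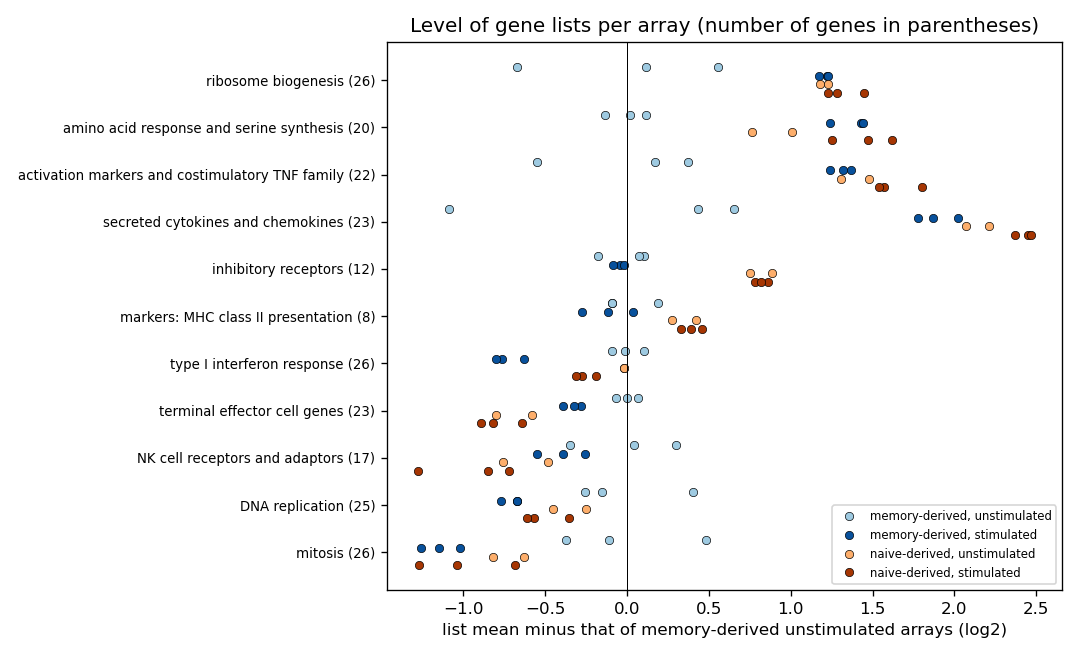
Mean log2 level of gene lists on each array, relative to the mean of the memory-derived unstimulated arrays (points are arrays, with the number of genes in parentheses). The cytokine list stood at 1.89 in memory-derived stimulated, 2.14 in naive-derived unstimulated and 2.43 in naive-derived stimulated arrays, and the inhibitory receptor list at -0.05, 0.82 and 0.82.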

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

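The tests of exchanged labels, of activation genes kept on, of degraded RNA and of NK cells were chosen only after the result was seen. The rule that a value must pass its bound by more than its spread was also added after the values were seen.

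The response to stimulation differed between origins in 401 genes by the interaction test, which compares 3 arrays with 3 in memory-derived and 3 with 2 in naive-derived effectors. The values below are the naive-derived minus the memory-derived response on the log2 scale, with adjusted p from 0.0066 (Tgfbr2) to 0.0497 (Gzmb). Without naive-derived unstimulated array 1 the count was 0 in limma (2600 at an unadjusted p below 0.05), and all of the genes named below lost the call. With the replicate block 26 genes passed, of which Ltb, Il1a, Socs3, Tgfbr2 and Isg20 are named here.

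Negative differences, in genes of several kinds, were found for the cytokines Il3 (-6.95), Il2 (-4.80), Il24 (-3.90), Il10 (-3.86), Il1a (-3.55, and -3.16 counted from the filter level, below which its memory-derived unstimulated arrays lay), Il23a (-3.02) and Tnf (-2.77), and for the activation markers Cd70 (-2.83) and Tnfrsf4 (-2.01). Immediate early and signalling genes included Ier3 (-2.43), Dusp4 (-1.89), Irf4 (-1.63), Nfkbid (-2.43), Nfkbib (-1.73), Stat5a (-2.59), Socs3 (-1.87) and Cflar (-1.56). Genes of metabolism and growth included Chac1 (-2.29), Asns (-1.54), Aldh18a1 (-1.17), Insig1 (-1.28), Dnajb9 (-1.39), Ncl (-1.29), Polr1a (-1.17) and Pes1 (-1.09). Serpinb6b, of a near-identical family, stood at -2.91.

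Positive differences were found for Ltb (2.95), Tbc1d10c (2.54), Crot (2.52), Ifi209 (2.41), Ypel3 (2.39) and Txnip (2.33). Receptors included Ccr2 (2.28), Ifngr1 (2.02), Tgfbr2 (1.95) and Nt5e (1.88), and signalling genes included Dgka (1.70), Prkcq (1.61), Ptpn6 (1.40) and Tnip1 (1.15). Interferon response genes were Rtp4 (1.49), Isg20 (1.46) and Parp14 (0.99), and cytotoxic genes were Fasl (0.90), Gzmb (0.86) and Ctsw (0.81).

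The first pattern weighed was that 2 genes passed for stimulation in naive-derived arrays, 1 of them below the filter level there, against 4675 in memory-derived ones. Leaving 1 unstimulated array out of the memory-derived comparison still left at least 3576 genes. This argues against the smaller group alone, but only for changes of memory-derived size. The naive-derived changes were smaller (slope 0.197), and the naive-derived design recovered 7.46% of simulated log2 changes of 0.5. Low power for small changes thus stays open. The naive-derived response had a positive slope on the memory-derived one in both experiments with a pair (0.179 and 0.152). This argues against exchanged labels in cells that responded strongly. An exchange between arrays of near-equal activation stays open, since slopes between naive-derived stimulated arrays reached 0.117 in size. Fully stimulated cells on both arrays labelled as unstimulated stay open too. The slopes of 0.179 and 0.152 both exceeded the largest slope between naive-derived stimulated arrays (0.117 in size), which was the bound set before. They did so by less than the SD of the 3 such slopes (0.0844). That SD depends on the order in which the arrays were subtracted, so it is a poor measure of spread and decides nothing. A biological explanation also stays open, that naive-derived cells may keep activation genes on: the activation list of the unstimulated arrays stood at 106% of the memory-derived response. Fully stimulated cells and activation genes kept on cannot be told apart, because both would put activation genes high on the arrays labelled naive-derived unstimulated. Nor does any array separate the origin of the cells from the time since their last restimulation.

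The next pattern was that memory-derived unstimulated array 3 stood apart from arrays 1 and 2, at 77.4 on the first principal component against 50.4 and 40.3. Degraded RNA is argued against, since the 3' minus 5' difference of actin on array 3 was 0.263 in log10 units, the lowest of its group (0.351 and 0.342 on the others), and that of GAPDH was the middle one. A shift of the same genes further towards rest could explain it and stays open. The deviation of array 3 correlated across genes with the naive-derived response at -0.171, short of the bound of -0.2 set before, with an SD of the other correlations of 0.0599. Behind that SD, the deviations of arrays 1 and 2 were taken from means that hold array 3. It is therefore not a separate measure of spread and decides nothing.

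The last pattern was that genes of NK cell receptors, such as Klre1, were lower in naive-derived arrays. NK cells in the memory-derived cultures may be a candidate source. Their marker Ncr1 had a mean of 0.444 in memory-derived and 0.368 in naive-derived arrays on the log10 scale, below the 60th percentile (0.685) on all 11 arrays. A value near the floor excludes nothing, so this stays open, although the cells were enriched for CD8. Effector T cells also express members such as Klrd1 (9.97 ± 0.512 in memory-derived unstimulated arrays, log2) and Klrk1 (7.53 ± 0.504), and Cd160 of this list is held by another list too.

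Among the 10 ways to split the 6 memory-derived arrays into 3 and 3, 1 gave as many genes, the real one with 4675, and the highest of the others gave 0. Of the 10 splits of the 6 stimulated arrays, 1 gave as many, the real one with 548, and the highest of the others gave 1. In both cases the splits are too few for a share under 0.05.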

How the results depend on the processing

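The scaling to hybridization controls was chosen after seeing the data. No named call reversed its sign in any alternative, among the 273 calls compared where all genes were tested. Normalizing by quantiles again changed nothing, as values were already so normalized, and pseudocounts were not tried on logarithms. Values near 0 are compressed, which limits dim genes.

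Main counts were 4675 and 2 for stimulation in memory-derived and naive-derived effectors, 3819 and 548 for origin in unstimulated and stimulated ones, and 401 for the interaction. A minimum log2 change of 1, which only filters the genes that passed and so repeats the 2-fold counts of the report, left 1330, 1293 and 238 for memory-derived stimulation and origin in unstimulated and stimulated effectors. With experiments 1 and 2 only, which are fewer arrays, 2755 genes passed for memory-derived stimulation (2640 shared), 1 for naive-derived stimulation, 258 for origin in stimulated effectors and 49 for the interaction. Fitting the groups alone gave 0 for naive-derived stimulation (limma; 1213 at an unadjusted p below 0.05) and 2376 for origin in unstimulated effectors.

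For naive-derived stimulation and the interaction the counts were 1 and 155 with control scaling, 0 (1384 at an unadjusted p below 0.05) and 174 with no filter, 1 and 1064 with the filter at the 60th percentile, and 13 and 1120 with a trended and robust fit. Array weights gave 1486 for the interaction. The cause was not tested. With the replicate block they were 0 (1354 at an unadjusted p below 0.05) and 26.

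Leaving out 1 array gave 0 to 5 genes for naive-derived stimulation, the 5 without naive-derived stimulated array 1. It gave 1843 to 4161 for origin in unstimulated effectors, 287 to 701 for origin in stimulated ones, and 0 to 1505 for the interaction. The 0 for the interaction had 2600 genes at an unadjusted p below 0.05. Where 1 array of the naive-derived unstimulated group remained, it was assumed to vary like the others. Gene lists called with an estimated correlation were 0 in all 5 comparisons, against 10, 7, 11, 12 and 11 in the order above, and experiments 1 and 2 alone gave 3 lists for naive-derived stimulation.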

Other observations

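Several fixed lists that the comparisons above leave out had members that changed without the list passing. In memory-derived effectors, stimulation changed 6 of 23 apoptosis regulators up and 11 down (6 and 12 adjusted over the list alone; adjusted p = 0.188), 11 of 28 negative regulators of T cell receptor signalling up and 7 down (11 and 9; 0.558), and 7 of 23 cytotoxic genes up and 5 down (the same, and 4 and 5 with control scaling; 0.856). Of 26 genes of naive and central memory cells, 3 rose and 9 fell (the same; 0.348). The counts were 6 and 9 of 24 cytokine receptor and STAT genes (9 and 9; 0.999), 3 and 4 of 20 glycolysis genes (the same, and 3 and 2 with control scaling; 0.999), and 6 and 4 of 20 sterol genes (6 and 7; 0.856). For chemokine receptors they were 2 and 7 of 19 (adjusted p = 0.088). Hk2, hexokinase 2, rose by 2.56 (SE 0.429), and by 1.97 without memory-derived unstimulated array 3.

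Without stimulation, 5 of 26 naive and central memory cell genes were higher and 9 lower in naive-derived cells (7 and 10 adjusted over the list alone, and 3 and 9 with control scaling; adjusted p = 0.799). Of 26 type I interferon response genes 5 were higher and 4 lower (3 and 4 with control scaling; adjusted p = 1). In stimulated cells, 2 of 20 sterol synthesis and uptake genes were lower and 0 higher, the same adjusted over the list alone (adjusted p = 0.0206, and adjusted p = 0.531 with an estimated correlation). With the replicate block the list passed (adjusted p = 0.0189) and 0 members did (limma; 2463 of all genes tested at an unadjusted p below 0.05), with control scaling 1 member was lower, and with experiments 1 and 2 only the list did not pass (adjusted p = 0.0795). Of 20 glycolysis genes, 0 passed in limma (1 higher and 1 lower adjusted over the list alone; adjusted p = 0.7).

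Markers of other cell types were also tested. The B cell list shifted up in naive-derived stimulated cells, with 1 of 11 genes higher and 1 lower, the same adjusted over the list alone (adjusted p = 0.0462, and adjusted p = 0.308 with an estimated correlation). In the same comparison the list of macrophages, dendritic cells and granulocytes had 1 of 13 higher and 2 lower (1 and 1 with the replicate block; adjusted p = 0.721), and that of erythroid cells and platelets had 0 of 7 over all genes (1 higher in limma adjusted over the list alone; adjusted p = 0.668). The sorting markers had 2 of 4 higher (1 with control scaling; adjusted p = 0.0963). In unstimulated cells 2 of 11 B cell markers were higher and 1 lower in naive-derived cells (the same adjusted over the list alone, 1 and 1 with control scaling, which reverses the sign of the list's median; adjusted p = 0.764), and 2 of 8 MHC class II markers were higher (4 adjusted over the list alone, 1 with the replicate block, 0 with control scaling; adjusted p = 0.0564). Of 13 markers of macrophages, dendritic cells and granulocytes, 2 were lower (the same adjusted over the list alone; adjusted p = 0.764). Single values were 1.30 for Ighm (adjusted p = 0.0221, 0.00118 to 0.148 over all alternatives), 0.82 for Pax5 (0.0232, 0.00179 to 0.19), 0.81 for Cd74 (0.0209, 0.0113 to 0.213), -1.67 for Cd68 (0.0018, 0.000325 to 0.0271) and -1.20 for Cd14 (0.0138, 0.00456 to 0.152). Without naive-derived unstimulated array 2, Ighm (0.141), Pax5 (0.19) and Cd74 (0.213, with a difference of 0.51) did not pass, and leaving out 1 array ended these calls in 4, 3 and 2 of 11 cases. Cd14 stood at -0.65 without array 1 of that group (0.152). No explanation was tested for these values.

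In the memory-derived stimulation comparison, 6893 genes had values that did not overlap between the groups, where chance gives 10% of genes for 3 arrays against 3. For origin in stimulated effectors, with as many arrays, the number was 3797. It was 3899 for naive-derived stimulation and 7896 for origin in unstimulated effectors. Chance gives a larger share in those 2 comparisons, which set 3 arrays against 2. Their numbers, such as 3899, are therefore not comparable with those of 3 arrays against 3, such as 3797.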
